A study of Rattus norvegicus with 4 samples.

How the data were processed

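Total RNA of 4 cultures of NR8383 cells exposed to Printex90 was measured on 1-colour Agilent rat expression arrays, 1 array per replicate, and the series design states that the replicates are biological. All 4 arrays share one slide and one scan, so slide and scan could not be tested as batches. Differences between slides or between scans cannot explain a difference between these arrays. Position on the slide and local defects of an array still can. The control group of the design was not analysed here, and no comparison between groups was made. P-values of the detection tests are across genes, which are not independent replicates.

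The deposited values are spot intensities on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes, and per the file headers the processed signal is background-subtracted with no normalization between arrays. Each array holds 62976 spots, of which 58717 are not controls, and these represent 45598 probes. The deposited files hold no gene names, so each probe's transcript accession was matched without its version to the RefSeq gene table of the GRCr8 assembly. This named 21109 probes for 16581 genes and left 24489 probes unnamed. The array grid was built on rn4 per the file headers, and no coordinates are given because the builds differ.

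Spots flagged by the scanner software as non-uniform or as population outliers were left out, which removed 750, 1092, 884 and 1551 non-control spots on replicates 1 to 4. Log2 processed signals were averaged over the spots of a probe, and the array's 75th percentile over all non-control probes was subtracted. That percentile was an intensity of 99.44, 83.77, 101 and 127.1, against a median processed signal of 14.87, 14.55, 13.93 and 22.83. A gene's level is that of the probe with the highest mean among its probes measured on all 4 arrays. For 52 genes, 26 of them detected on all 4 arrays, this passed over a probe with a higher mean that had a spot left out on some array. Of 3658 genes with more than 1 probe, 969 were called detected while at least one of their probes was not. A probe was detected on an array when any spot of it was well above background by the scanner software's flag, and a gene when any of its probes was. The number of arrays, 4, limits the precision of each value.

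Before the data were examined, 21 gene lists and 12 lists of cell type markers were fixed. The genes named with values come from the first 2 measured members of each gene list, the 10 genes with the largest SD among those detected on all 4 arrays, and the members of the marker lists detected on all 4 arrays. Other members are named beside the counts, and genes of further families were looked at after the data were seen. For each list the members detected on all 4 arrays were set against all other named genes with a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over the 33 lists at a threshold of 0.05. The spread of a list is the median SD of its detected members, for lists with at least 5, given as a percentile among 10000 random lists of detected genes drawn from the same 20 bins of mean level. Single spots of probes printed 3 or more times were fitted with limma, with the array as a factor, and tested with a moderated F test.

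A map of bright regions was made after the data were seen. Blocks of 16 rows and 8 columns were marked on an array where over 10% of the spots of unnamed probes stood 1 log2 unit or more above every other array. The alternatives fixed beforehand were another detection flag, 3 of 4 arrays, all probes of a gene, flagged spots kept, quantile normalization, the array median, the mean of all probes, no detection filter, and leaving out each replicate. Added after the data were seen were the removal of the marked blocks, the 75th percentile over detected probes, and normexp on the median signals with an offset of 50. Blocks marked on any array were removed from all 4 arrays. For detection, a gene left without a spot counted as not detected.

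The methods were tested on simulated data. With the spot noise of the 1067 replicated probes and 1 array shifted, limma recovered 77.61% of probes shifted by 0.25 log2 units, 100% of those shifted by 0.5 and 100% of those shifted by 1, with 8 calls among 867 unshifted probes. Among the 8424 detected genes, the spread lay above the central 95% of random lists in 91 of 100 lists of 9 genes whose simulated SD was multiplied by 2 and in 0 of 100 unchanged lists. The random lists were drawn gene by gene, so the percentiles of spread make no allowance for members of a list that vary together. Among the 16581 genes, Fisher's exact test gave an unadjusted p under 0.05 for 98 of 100 lists of 12 genes with a detection chance of 0.95 and for 1 of 100 lists at the overall chance. The software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.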

Results

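Gene expression was measured in NR8383 cells, a macrophage line derived from rat lung lavage, after 4 h with Printex90, a commercial carbon black, at the labelled dose of 0.9 cm2/cm2. The labels add the abbreviation ALI, which commonly stands for air-liquid interface. One group of 4 arrays was analysed, 1 array for each biological replicate. The series design also describes untreated cells, which were not analysed here, so no value below is a change caused by the particles. What the 4 arrays can show is which genes had a signal in the exposed cells, how closely the replicates agreed, and which gene groups differed between replicates. A gene's level is given as log2 intensity relative to its array's 75th percentile, and a level of 0 therefore lies at that percentile. Levels of different genes come from different probes and are not ranked against each other.

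In the exposed cells, 8424 of 16581 named genes (50.81%) had a signal well above background on all 4 arrays. Another 6116 genes were not well above background on any array, and 2041 were detected on some arrays. Each array detected between 8917 and 9985 genes, with a mean of 9322 ± 463 (SD, n = 4). Replicate 4 gave the highest number, and of the 1014 genes detected on exactly 1 array 661 were detected on that array. Olfactory receptor genes, which sense odorants in the nose and serve here as a background, were detected on all 4 arrays in 41 of 1161 cases (3.531%). On single arrays this number was 81, 99, 69 and 176 for replicates 1 to 4. None of the 308 negative-control spots was well above background on every array, and no spot was saturated.

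Most macrophage identity genes were detected. The other named genes, against which each list was set, include the 1161 olfactory receptor genes, of which 41 were detected on all 4 arrays. These lower the share that a list is compared with, and no test was run without them. Of 14 macrophage identity genes, 12 were detected on all 4 arrays (85.71%), against 50.78% of the other named genes (Fisher's exact test, two-sided, adjusted p = 0.048). They included Cd68, a lysosomal glycoprotein of macrophages, at a level of 7.56 ± 0.21 (SD, n = 4), and Csf1r, the receptor for macrophage colony-stimulating factor, at 1.24 ± 0.18 (SD, n = 4). Adgre1 was detected on 2 arrays. This call did not hold when detection on 3 of the 4 arrays was enough (adjusted p = 0.092), with the less strict detection flag (adjusted p = 0.093), without replicate 2 (adjusted p = 0.055) or without replicate 3 (adjusted p = 0.053), in a range of 0.013 to 0.093 over 9 alternatives.

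Markers of alveolar macrophages and receptors that take up particles were mostly detected, without passing the test. Pparg, a nuclear receptor needed for alveolar macrophage development, had a level of 6.25 ± 0.24 (SD, n = 4), and 10 of 14 measured alveolar macrophage markers were detected on all 4 arrays (adjusted p = 0.24, Fisher's exact test). Among the receptors, Cd36 had a level of 8.19 ± 0.09 and Msr1, a scavenger receptor, one of 2.06 ± 0.29 (SD, n = 4 for both). Marco, the scavenger receptor best known for binding inhaled particles, was detected on 1 array alone, with a measured mean of -3.66 ± 0.92 (SD, n = 4). In all, 10 of 12 measured uptake receptors were detected (adjusted p = 0.086, Fisher's exact test), and Colec12 was detected on no array. The 2 probes of Cd36 gave different levels, and their mean was 4.77.

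All 14 lysosome genes were detected on all 4 arrays, against 50.76% of the other genes (adjusted p = 0.0021, Fisher's exact test). Ctsd, the aspartic protease of lysosomes, had a level of 10.47 ± 0.13 and Lamp1, a protein of the lysosomal membrane, one of 5.50 ± 0.13 (SD, n = 4 for both). Proliferation genes showed the same completeness, with 12 of 12 detected (adjusted p = 0.0041, Fisher's exact test). Mki67, a marker of cycling cells, had a level of 3.11 ± 0.18, and the cyclin gene Ccnb1 one of 1.90 ± 0.13 (SD, n = 4 for both). Over the 4 probes of Mki67 the mean was 1.80. Both calls held under each of the 9 alternatives for detection.

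Genes of several stress programmes were detected more often than other genes. All 12 genes of the unfolded protein response were detected (adjusted p = 0.0041, Fisher's exact test), including the chaperone gene Hspa5 at 6.87 ± 0.16 and the transcription factor gene Ddit3 at 4.95 ± 0.28 (SD, n = 4 for both). In the heat shock and metal response, 9 of 9 measured genes were detected (adjusted p = 0.026, Fisher's exact test), with the metallothionein gene Mt1 at 4.52 ± 0.32 and the inducible chaperone gene Hspa1a at -1.22 ± 0.12 (SD, n = 4 for both). Hspa1a was detected on all arrays by 1 of its 2 probes, and their mean was -3.08. Of 12 targets of NRF2, the transcription factor of the oxidative stress response, 11 were detected (adjusted p = 0.035, Fisher's exact test). Hmox1, which degrades haem, had a level of 5.99 ± 0.34 and the quinone reductase gene Nqo1 one of -0.31 ± 0.19 (SD, n = 4 for both), while Gclm was detected on no array. With the less strict detection flag the heat shock and NRF2 calls were lost (adjusted p = 0.093 for both, Fisher's exact test). Over the alternatives the adjusted p ranged from 0.014 to 0.093 and from 0.012 to 0.093. The NRF2 call was also lost when the bright regions of any array were left out on all 4 arrays (adjusted p = 0.06, Fisher's exact test). Genes left without a spot then counted as not detected, so this does not show that a bright region made the call.

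Inflammatory genes were detected in part. Of 14 inflammatory cytokines, chemokines and related enzymes, 9 were detected on all 4 arrays (adjusted p = 0.47, Fisher's exact test). Il1b, the gene of the cytokine interleukin-1 beta, had a level of 7.67 ± 0.44 and Tnf one of 5.46 ± 0.26 (SD, n = 4 for both), while Il6, Il12b and Ptgs2 were detected on no array. Among NF-kB targets and regulators 8 of 9 were detected (adjusted p = 0.086, Fisher's exact test), with the inhibitor gene Nfkbia at 3.92 ± 0.14 and Nfkb1 at 1.89 ± 0.20 (SD, n = 4 for both). In the inflammasome list 6 of 7 were detected (adjusted p = 0.21, Fisher's exact test), with the sensor gene Nlrp3 at 2.28 ± 0.27 and the protease gene Casp1 at 1.92 ± 0.20 (SD, n = 4 for both). The Toll-like receptor list gave 9 of 12 (adjusted p = 0.21, Fisher's exact test), with Tlr2, a receptor for bacterial lipoproteins, at 5.58 ± 0.18 and Tlr4, the receptor for lipopolysaccharide, at 1.92 ± 0.08 (SD, n = 4 for both). Different probes of Tnf, Nfkb1 and Nlrp3 gave different levels, and the mean over all probes was 2.53 for Tnf, 0.05 for Nfkb1 and 0.70 for Nlrp3.

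Interferon response genes were detected in 9 of 12 cases and immediate early genes in 8 of 13 (adjusted p = 0.21 and 0.6, Fisher's exact test). Isg15, a ubiquitin-like protein, had a level of 1.77 ± 0.25 and the antiviral GTPase gene Mx1 one of 1.08 ± 0.25, while Fos, a part of the transcription factor AP-1, had one of -2.10 ± 0.60 (SD, n = 4 for all). Egr1 was detected on 3 arrays. Of the p53 targets 9 of 12 were detected (adjusted p = 0.21, Fisher's exact test), with Cdkn1a, an inhibitor of the cell cycle, at 5.67 ± 0.10 and Mdm2, the ubiquitin ligase of p53, at 2.20 ± 0.09 (SD, n = 4 for both). Over its 2 probes Cdkn1a had a mean of 2.80. The hypoxia list gave 10 of 12 (adjusted p = 0.086, Fisher's exact test), with the glucose transporter gene Slc2a1 at 5.91 ± 0.17 (SD, n = 4) and no detection of Vegfa by any of its 3 probes.

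Targets of the aryl hydrocarbon receptor, which responds to polycyclic aromatic hydrocarbons, were mostly not well above background. Cyp1a1 was detected on no array and Cyp1b1 on 1, with measured means of -5.23 ± 0.23 and -3.31 ± 0.08 (SD, n = 4 for both). Over the 3 probes of Cyp1b1 the mean was -4.49. Of the 7 measured genes of this list only Ugt1a6 was detected on all 4 arrays, and Cyp1a2, Ahrr, Aldh3a1 and the receptor gene Ahr were on none (14.29% against 50.82% of other genes, adjusted p = 0.14, Fisher's exact test). With the less strict flag the share was 42.86% (adjusted p = 0.52). The list passed the test as detected less often when all probes of a gene had to be detected (adjusted p = 0.048, in a range of 0.048 to 0.52 over the alternatives).

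Class II antigen presentation and alternative activation were each detected in 4 of 11 genes (adjusted p = 0.43 for both, Fisher's exact test). Cd74, the invariant chain of class II molecules, and RT1-Da, a class II alpha chain, were not well above background on any array. Neither was Cd163, a haemoglobin scavenger receptor, whereas Arg1, the arginase of alternatively activated macrophages, had a level of 4.56 ± 0.14 (SD, n = 4). Among matrix remodelling genes 5 of 11 were detected (adjusted p = 0.77, Fisher's exact test), including Mmp12, the macrophage elastase, at 2.53 ± 0.13 and Mmp9, a gelatinase, at 0.73 ± 0.27 (SD, n = 4 for both). The lipid and cholesterol list gave 11 of 13 (adjusted p = 0.062, Fisher's exact test), with the cholesterol exporter gene Abca1 at -0.39 ± 0.10 (SD, n = 4). When all probes of a gene had to be detected, the lipid, NF-kB and uptake receptor lists passed the test as detected more often (adjusted p = 0.02, 0.037 and 0.028), in ranges of 0.02 to 0.25, 0.037 to 0.26 and 0.028 to 0.25 over the alternatives.

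Markers of other cell types were detected less often or no more often than other genes. None of 14 genes typical of organs outside the lung was detected on all 4 arrays (adjusted p = 0.0016), and 1 of 10 general epithelial genes (Elf3, -2.06 ± 0.26) and 1 of 10 fibroblast genes (Dcn, 0.20 ± 0.21) were (adjusted p = 0.043 for both, Fisher's exact test; SD, n = 4). Of the markers of lung epithelium, Napsa at 5.68 ± 0.19 and Etv5 at 3.84 ± 0.08 were the 2 of 9 detected for alveolar type II cells, and Hopx, Foxj1 and Tp63 the 3 of 9 for alveolar type I and airway cells (SD, n = 4; adjusted p = 0.18 and 0.41, Fisher's exact test). Hopx (-2.32 ± 0.32), Foxj1 (0.91 ± 0.22), Tp63 (3.15 ± 0.10) and the endothelial gene Vwf (4.78 ± 0.15) each rested on 1 probe while their other probes were not detected on all arrays (SD, n = 4). Their means over all probes were -3.82, -1.36, -1.98 and 0.41. With Cdh5 (-0.98 ± 0.58), Vwf made 2 of 8 endothelial genes (adjusted p = 0.24, Fisher's exact test; SD, n = 4). The organ call was lost with the less strict flag (adjusted p = 0.13, range 0.00063 to 0.13), the epithelial call when all probes were required (adjusted p = 0.061, range 0.025 to 0.061), and the fibroblast call under both (adjusted p = 0.57 and 0.061, range 0.035 to 0.57) and without replicate 2 (adjusted p = 0.13). The epithelial and fibroblast calls were also lost without the bright regions (adjusted p = 0.06 for both, Fisher's exact test). Both shares stayed at 10%, while that of the other genes fell from 50.83% to 49.1%, since genes left without a spot counted as not detected. The fibroblast call was also lost when 3 arrays were enough (adjusted p = 0.11, Fisher's exact test).

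Blood cell markers gave 3 of 10 T cell genes, with Cd28 at 1.92 ± 0.14, Lck at -0.34 ± 0.22 and Cd3d at -0.44 ± 0.17 (SD, n = 4 for all; adjusted p = 0.28, Fisher's exact test). For B cells the count was 3 of 8, with Fcrla at 3.01 ± 0.23, Pax5 at 0.60 ± 0.19 and Ebf1 at 0.17 ± 0.11 (SD, n = 4 for all; adjusted p = 0.53, Fisher's exact test). NK cells gave 2 of 9, namely Nkg7 (-0.43 ± 0.26) and Gzmb (-1.61 ± 0.48), and neutrophils 2 of 9, namely Lcn2 (3.16 ± 0.43) and Camp (3.01 ± 0.34; SD, n = 4 for all; adjusted p = 0.18 for both lists, Fisher's exact test). One gene each was detected for mast cells (Hdc, -1.78 ± 0.42) and erythroid cells (Hba-a1, 2.04 ± 0.20), of 9 measured (SD, n = 4; adjusted p = 0.059 for both, Fisher's exact test). Cd28, Gzmb and Hdc rested on 1 of 2 probes and Ebf1 on 2 of 5, and the means over all probes were -1.57, -2.71, -2.60 and -2.08. When all probes of a gene were required, no mast cell marker and no alveolar type I or airway marker was detected, and both lists then passed as detected less often (adjusted p = 0.02 for both, in ranges of 0.02 to 0.093 and 0.02 to 0.82).

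**Figure D1:**
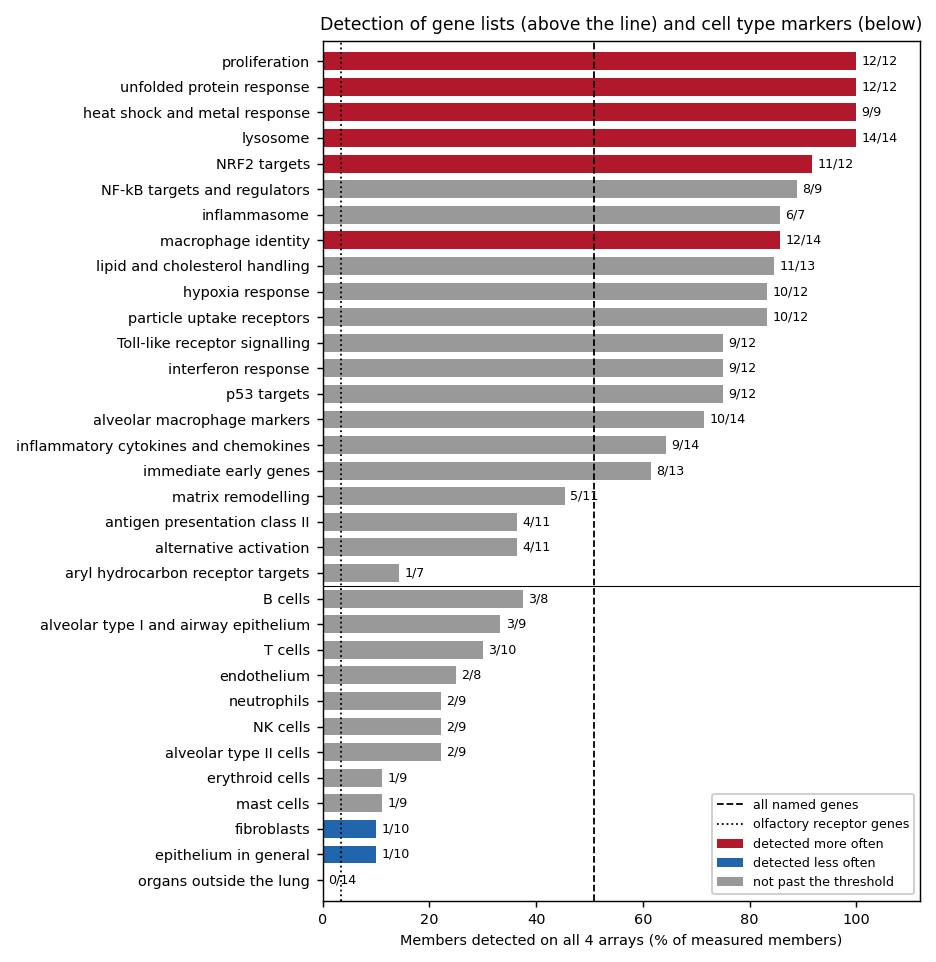
Percent of the measured members of each gene list (above the horizontal line) and each cell type marker list (below it) that were detected on all 4 arrays, with the counts beside the bars. The dashed line marks all named genes (50.81%) and the dotted line olfactory receptor genes (3.531%); lysosome, proliferation, unfolded protein response and heat shock lists reach 100%, and no organ marker is detected.

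Replicates agreed closely for most genes. Over the 8424 detected genes the median SD of the log2 level was 0.165, or 1.121-fold, with a 5th to 95th percentile range of 0.060 to 0.411. An SD above 0.5 was found for 205 genes (2.434%). Each array's median distance from the mean of the other 3 was 0.153, 0.129, 0.157 and 0.146 for replicates 1 to 4, and the correlation of 2 arrays across genes, which are not independent replicates, ranged from 0.9905 to 0.9935. Scaling to the array median, which lies near the background, raised the median SD to 0.390.

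The 10 genes with the largest SD were led by Krt33b, a hair keratin gene, with levels of 9.83, -0.76, -1.04 and -0.78 on replicates 1 to 4. Its single spot on replicate 1 lies among spots that were also brighter on that array, by a median of 4.38 on the log2 scale. Or2l13, an olfactory receptor gene, reached 2.99 on replicate 3 against -1.84 or less on the other arrays, and Smpd4, Pcif1l1 and Tysnd1 also stood highest there. The spots of these 4 genes lie in a bright region of replicate 3 that holds 2.841% of the spots. Pdxp, a phosphatase gene, had levels of 2.82, 6.33, 4.22 and 8.16, and Dlx3, a homeobox gene, 6.98, 9.43, 8.11 and 9.82. Mapk3, which encodes the kinase ERK1, had levels of 8.83, 11.34, 9.93 and 10.87, so that all 3 were lowest on replicate 1 and next lowest on replicate 3. Tmem63c was low on replicate 3 (-4.91) and Ly6g5c on replicate 1 (-5.25), and for neither was any single probe detected on all 4 arrays. The other probe of Ly6g5c read 3.72, 3.53 and 3.43 on replicates 1 to 3, and its spot on replicate 4 was left out, so the low value on replicate 1 is that of the weaker probe alone. The mean over the measured probes of Ly6g5c was -0.71, with replicate 4 given by the weaker probe alone.

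**Figure D2:**
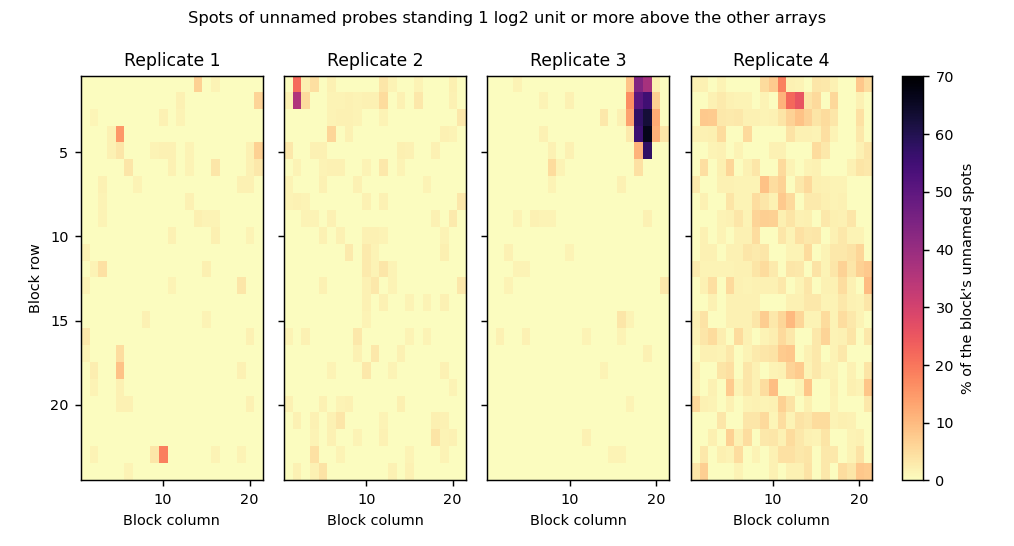
Percent of spots of probes without a gene name, in blocks of 16 rows by 8 columns, whose log2 level was 1 or more above that of every other array, for each of the 4 arrays. On replicate 3 the share reaches 66.67% in one block, and 14 of 504 blocks exceed 10%, against 2, 2 and 5 blocks on replicates 1, 2 and 4.

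The cytokine and interferon response lists varied between the replicates more than random lists of detected genes did. The 9 detected cytokines and chemokines had a median SD of 0.365, above 99.99% of 10000 random lists of the same size matched on level, whose median was 0.149. They lay 0.36 above their 4-array mean on replicate 3, where 7 of the 9 were highest, and at -0.33 on replicate 4, where 8 were lowest. Il1b, for example, had levels of 7.52, 7.68, 8.27 and 7.22 on replicates 1 to 4, and Tnf 5.30, 5.51, 5.81 and 5.24. The interferon response list had a median SD of 0.251 (percentile 98.7) and lay at 0.25 on replicate 1 and -0.23 on replicate 4. Of the 18 lists with at least 5 detected members, these 2 lay above the central 95% of their random lists and none lay below it. Immediate early genes came next, at the 94.17th percentile and 0.30 on replicate 3. Their spread passed the limit under quantile normalization and with the array median. Fos was at -1.24 on replicate 3 and at -2.11 or less elsewhere, with weak intensities of 23, 15, 43 and 22 on replicates 1 to 4. Without the bright regions 7 of the 8 members were left, at 0.27 on replicate 3. Replicate 3 also stood higher in the unfolded protein response list, at 0.18 (percentile 99.73, 8 of 12 members highest there). The NRF2 list lay there at 0.15 (percentile 97.96, 6 of 11), so cytokine genes were not alone in this. Percentiles as far out as that of NRF2 were not particular to replicate 3. Lysosome (99.02), lipid (98.77) and p53 (98.54) lists had them on replicate 4, and NF-kB (0.99) and NRF2 (1.33) on replicate 1. With 18 lists on 4 arrays, some of these arise by chance. Detected genes in general lay a median of 0.040 above the mean of the other arrays on replicate 3. Of the macrophage identity genes 7 of 12 were highest there too, at the 88.97th percentile. Without replicate 3 the spread of the cytokine list fell to the 76.9th percentile. The list then still lay at -0.22 on replicate 4 (percentile 0.07, 8 of 9 lowest) and at 0.16 on replicate 2 (percentile 99.45, 7 of 9 highest). The spread of the interferon list fell to the 74.77th percentile without replicate 4 and the 97.17th without replicate 1. The cytokine and interferon lists also lost their place in spread with normexp on the median signals (92.79 and 86.25), and the interferon list with no detection filter (96.47).

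The sizes of these deviations depended on the processing. With no detection filter, which adds members near background, the cytokine list lay at 0.22 on replicate 3, at the upper edge of the central 95% of random lists, and at -0.15 on replicate 4, inside it (percentile 10.26). Immediate early genes then lay at 0.05 on replicate 3 (percentile 85.46). With normexp they lay there at 0.17 (percentile 99.49). The interferon list on replicate 1 lay at 0.15 without the bright regions (percentile 98.78) and at 0.14 with normexp (percentile 99.07). With normexp it lay on replicate 4 at -0.08 (percentile 1.2). Without the bright regions its value on replicate 3 went from -0.05 to 0.07. Scaling to the array median moves all genes of an array alike and leaves the percentiles of the deviations as they are, but it brought the cytokine list to 0.79 on replicate 3 and -0.59 on replicate 4, and immediate early genes to 0.74 on replicate 3. The interferon list was then at 0.34, -0.23, 0.38 and -0.49 on replicates 1 to 4, highest on replicate 3 and lowest on replicate 4 like the cytokine list.

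**Figure D3:**
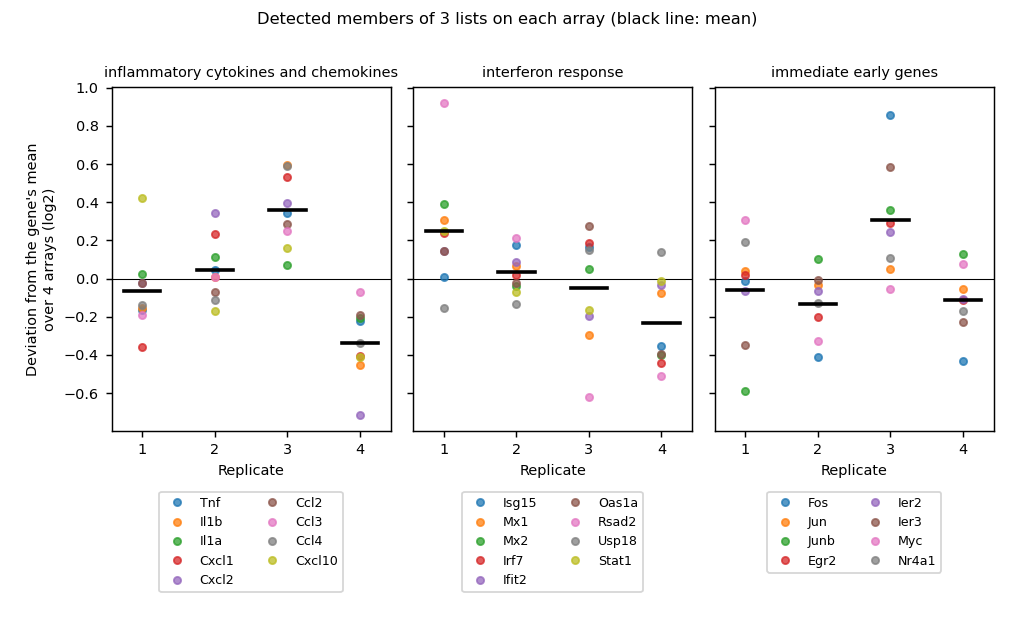
Deviation of each detected member from its own mean over the 4 arrays (log2), by replicate, for the cytokine, interferon and immediate early gene lists; points are genes and black lines their mean. Cytokine genes average 0.36 on replicate 3 and -0.33 on replicate 4, and interferon response genes 0.25 on replicate 1 and -0.23 on replicate 4.

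Probes printed in several copies allow the arrays to be set against the noise between spots. Of 1067 such probes detected on all 4 arrays, 936 (87.72%) differed between arrays after Benjamini-Hochberg adjustment (limma moderated F test). The differences were small: the SD between array means had a median of 0.127 and the SD between spots of one array a median of 0.109, both on the log2 scale. The share depended on the scaling, with 70.48% under quantile normalization and 98.97% with the array median. Each array is a separate culture, so a difference beyond spot noise marks no array as unusual.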

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

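All tests of explanations in this part were chosen after the result was seen, except the one on other probes of the genes high on replicate 3. A replicate standing far from the other 3 was found in 10 of 89 values tested with Dixon's ratio, at a threshold passed by about 1 in 20 values by chance. Of these, 5 were among the 10 genes chosen for the largest SD, a choice that favours a lone array, and the other 79 values gave 5, against 3.95 by chance. The design gives no biological explanation for a difference between replicates of one group, and none was tested against a group.

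Krt33b stood far above the other arrays on replicate 1 (Dixon's ratio 0.974). Hair keratin RNA in that replicate is argued against, since the other 33 keratin and keratin-associated genes detected on any array deviated there by a median of 0.01 on the log2 scale, with quartiles of -0.46 and 0.26. A defect of its spot alone is argued against as well, since 68.18% of 22 neighbouring spots were 1 log2 unit or more higher on replicate 1. The neighbours' median deviation was 4.38 (quartiles 0.59 and 10.85), so a bright patch on the array is the likely source. Krt33b has 1 spot and 1 probe, so its level on replicate 1 cannot be had from elsewhere.

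Or2l13 (Dixon's ratio 0.841) and Smpd4 (0.875) stood far above the other arrays on replicate 3, and 21 detected genes were 1 log2 unit or more higher there than on every other array, against 1, 2 and 4 genes on replicates 1, 2 and 4. Genes standing low on 1 array alone numbered 13, 3, 15 and 11 on replicates 1 to 4. Of the 21, 16 (76.19%) have their spot in the blocks that unnamed probes mark as bright on replicate 3, which hold 2.841% of spots, short of the 80% set for the patch to account for the whole group. Among 153 named probes with copies inside and outside these blocks, 127 were higher inside on that array. Over all 153 the median of inside minus outside was 0.21 (quartiles 0.06 and 0.48). A higher transcript level in replicate 3 stays open, because 1 other detected probe of the 21 genes lies outside the blocks, with a deviation of -0.38. A local patch may therefore account for many of these genes. For the 5 outside the marked blocks, among them Prpf19 and Gba2, named after their values were seen, the blocks cannot decide. Only 86.05% of the unnamed spots standing high on replicate 3 lie inside the marked blocks, and the neighbours of these 5 spots were not examined.

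The cytokine list was high on replicate 3 and low on replicate 4. The bright patch is argued against as the whole cause, since without the marked blocks the 8 members left lay at 0.37 on replicate 3 and at -0.33 on replicate 4. Under quantile normalization the deviation on replicate 3 was 0.32, at the 99.96th percentile of random lists. That percentile could hardly have moved, since the random lists are matched on level and share the array's scaling. It therefore does not test scaling between arrays. The size of the deviation did depend on it, with 0.36 in the main setting and 0.79 with the array median. With normexp on the median signals, which changes the signal and the correction together, replicate 3 lay at 0.24. This speaks against background subtraction as the whole cause there. Replicate 4 went to -0.14, so the part of background subtraction in the size of its low level stays open. Among random lists under the same correction these deviations were still extreme, at percentiles 100 and 0.01. The list's spread fell to the 92.79th percentile. No biological explanation was tested, and the handling of cells and RNA, which the labels do not give per replicate, stays open.

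Replicate 4 had a higher median processed signal than the other arrays (Dixon's ratio 0.894). The inflammasome list was lowest on replicate 3 (0.883), at a mean deviation of -0.13. Cd68 was lowest on replicate 1 (0.95), at 7.24 against 7.66 to 7.68. Hopx was lowest on replicate 3 (0.933), at -2.80, and Nkg7 highest on replicate 4 (0.895), at -0.05. Tmem63c was lowest on replicate 3 (0.878) and Ly6g5c on replicate 1 (0.905), by the weaker of its 2 probes, while the other read 3.72 there. Outside the main measurement, 6738 probes without a gene name here were detected on all 4 arrays, 27.51% of the unnamed probes.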

How the results depend on the processing

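Removal of the bright blocks, normexp on median signals and the percentile over detected probes were chosen after the data were seen; normexp on mean signals was not run, since the files hold no such column. No paired analysis was possible because there is 1 group. The number of detected genes stayed within 1.5 times the main count under all 9 alternatives for detection (7455 to 10236). The replicated probes that differ between arrays also stayed within it, under a partly different set of alternatives (735 to 1108 of those tested, main 936). They were not tested with the other detection flag, 3 of 4 arrays, all probes of a gene or flagged spots kept. The lysosome, unfolded protein response and proliferation lists kept their calls under all 9, and the other 6 called lists lost theirs under at least one. The cause was not tested except where named. With the less strict flag, which counts more genes as detected, lists detected more often went from 6 to 3 and less often from 3 to 1, with shares of 91.67% for NRF2, 100% for heat shock, 92.86% for macrophage identity, 50% for fibroblasts and 35.71% for organs. Detection on 3 arrays ended the calls of macrophage identity (85.71%) and fibroblasts (20%). Requiring all probes ended those of epithelium and fibroblasts (10% each) and made calls of NF-kB (88.89%), lipids (84.62%), uptake receptors (83.33%), aryl hydrocarbon receptor targets, mast cells and alveolar type I cells (0% each). Without the bright blocks 1 list was detected less often, and NRF2 (83.33%), epithelium and fibroblasts (10% each) lost their calls. Genes left without a spot counted there as not detected, in the lists and among the other genes. Leaving out 1 replicate gave 85.71% throughout for macrophage identity and 10% to 20% for fibroblasts. The median SD (0.165) and the median distance of an array (0.150) became 0.390 and 0.382 with the array median, 0.178 and 0.167 with flagged spots kept, 0.251 and 0.211 with no detection filter, which admits probes at background, and 0.142 and 0.121 with normexp; leaving out 1 replicate gave an SD of 0.151 to 0.162. Lists with a wide spread numbered 4 with the array median, 1 with no filter, 1 with normexp and 1 to 2 when 1 replicate was left out. Percentiles of spread with normexp were 92.79 for cytokines, 86.25 for interferon and 99.41 for heat shock, and with no filter 96.47 for interferon. Immediate early genes reached 99.54 with the array median and 99.19 with quantile normalization, and the unfolded protein response 98.3 with the array median. One list became narrow with flagged spots kept (lysosome, 0.31) and 1 with the mean of all probes (Toll-like receptors, 2.015). Leaving out 1 replicate gave 76.9 to 100 for cytokines, 74.77 to 99.8 for interferon and 73.11 to 99.25 for immediate early genes. Of the levels of single genes and the olfactory count, 72 values moved by more than their spread and 661 did not. Normexp on the median signals, which changes signal and background correction together, moved 48 of 73 levels, and the mean of all probes 18; olfactory genes numbered 145 with the less strict flag and 63 with 3 arrays. Signals near background limit the low levels.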

Other observations

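Further gene families were looked at after the data were seen, with no test. Of 33 chemokine ligand genes 14 were detected on all 4 arrays, among them Ccl6 at a level of 7.56 ± 0.14 and Ccl9 at 6.85 ± 0.07, while 12, including Cxcl12, Cxcl13 and Ccl19, were detected on none. Chemokine receptors gave 6 of 17, with Ccr1 at 0.99 ± 0.17 (SD, n = 4). Of 30 interleukin genes 6 were detected, namely Il1a, Il1b, Il18, Il7, Il36b and Il17b, and 19 were on no array, including Il6, Il10 and Il33. Of 6 interferon genes only Ifna4 was detected (-0.81 ± 0.14), and probes of this family can share signal between close copies.

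Of the subunit genes of the V-ATPase, the proton pump that acidifies lysosomes, 15 of 21 (71.43%) were detected on all 4 arrays, and of the cathepsin genes 9 of 17 (52.94%), against 50.81% of all named genes. Ctsz had a level of 6.75 ± 0.05 and Ctsa one of 7.11 ± 0.13, while Ctsk and Ctsg were on no array (SD, n = 4). C-type lectin genes gave 11 of 25, with Clec7a, a receptor for fungal glucans, at 6.35 ± 0.16, and glutathione S-transferases 8 of 22. Krt79, a keratin gene, had a level of 8.45 ± 0.11 (SD, n = 4), unlike the general epithelial keratins Krt8, Krt18 and Krt19, none of which was detected on all arrays.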
